A study of Mus musculus with 20 samples.

How the data were processed

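DNA from the tails of 10 mice of the inbred strain C57BL/6JNrs was compared with DNA of 1 reference male of the same colony by array comparative genomic hybridisation, in which a test and a reference DNA carry different dyes and compete for the same probes. The mice were 1 father, 1 mother and 8 of their progeny. Each mouse was hybridised on 2 arrays, once labelled with Cy5 and once with Cy3, per the labels. The 20 arrays lay on 5 slides, read from the array numbers of the file headers, with 2 mice per slide: father and mother on slide 1, progeny 1 and 2 on slide 2, progeny 3 and 4 on slide 3, progeny 5 and 6 on slide 4, and progeny 7 and 8 on slide 5. The labels tie the family to a series on males exposed to 0.05 mGy per day of gamma rays for 400 days, but the design text calls the male of this family non-irradiated. The irradiation of the father is therefore unsettled here, and no comparison below rests on it.

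The array belongs to a second screening step. According to the design text, it holds probes that departed from the reference in a first, wider array of the same family, with neighbouring probes added at high density. Its loci are therefore selected and do not sample the genome evenly. Each array had 160338 spots that were not controls, for 156258 probes, of which 156207 were autosomal, 48 lay on X and 3 on Y. The median spacing of neighbouring probes was 91 bp. Positions are those of build mm9, per the file headers. The files used here pair no probe with a gene, and the gene table at hand is of another build, so regions are given by position only. The gene lists and the named genes planned before the data were examined were not analysed here.

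The deposited scanner files give spot intensity values made with Agilent Feature Extraction 10.7.1.1, per the file headers. The processed intensity of each channel was background subtracted, spatially detrended and dye normalised by a linear factor per channel, per the file headers. The median spot and local background intensity columns are uncorrected, per the file headers. The deposited value table holds log2 ratios of reference over mouse on every array. Set against the log10 ratio column that the authors' scanner files give, it differed by 1 constant per array. Its scale and direction were settled by that comparison, and the origin of the constants is not given in the sources used here.

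From the processed intensities, the log2 ratio of red over green was taken for each spot, spots flagged as outliers were left out (100 to 177 per array), and the sign was turned so that a positive value means more DNA in the mouse than in the reference. Each array was centred on the median of its autosomal probes, without loess or quantile normalisation. Spots of a probe were averaged, then the 2 dye orientations of a mouse, so that a mouse is 1 replicate. No spot was saturated. Between 93.3% and 99.5% of spots were well above background in the mouse channel. The standard deviation of the log2 ratios was 0.44 on the progeny 2 array with the mouse in Cy3 and 0.13 to 0.19 on the other arrays. The number of arrays, 2 per mouse, limits the precision.

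Autosomal probes were averaged in 10 kb windows with at least 3 probes (6466 windows). With limma 3.58.1 under R 4.3.3, the progeny mean was tested against 0 and against the mean of the parents. A window was called at an adjusted p (Benjamini-Hochberg) under 0.05 and a log2 ratio of at least 0.3 in size. The reference was 1 mouse, so the first test leaves out the spread between reference mice. Its p-values measure the spread between the progeny of this family. In the second test each parent is 1 mouse, assumed to vary like the progeny. Mother and father were compared without a test, counting windows that differed by at least 0.3, and by at least 0.15 in each orientation.

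Regions were called in each mouse by interval scores, the sum of log2 ratios over a run of probes divided by the noise times the square root of their number, taking the best run and repeating on either side. A call needed a score of 6, 3 probes, a mean of 0.3 in size, and 0.15 with the same sign in each orientation. The noise came from the median absolute deviation of the difference between orientations. A run was limited to 5000 probes, a limit raised after the chromosome 4 call had first been cut short. Values on X and Y had the chromosome median of the mouse subtracted for calling. Calls of different mice with the same sign and a share of at least 0.5 of the shorter call's probes in common were merged, and values are means over the probes of the merged region, so a calling mouse can lie under 0.3 there. A region counted as absent from a parent when no call of that parent overlapped it and the parent's value was under 0.5 of the lowest calling progeny's. Numbers of regions per mouse were compared by a two-sided exact permutation test over 45 splits. The same caller was run on the difference between orientations, which cancels copy number but not dye bias.

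Regions are named by a rule set before the data were examined: up to 10 called in the most mice, up to 10 called in some mice with the largest mean over the calling mice, and up to 10 called in progeny and in neither parent. For windows, adjacent calls of one sign count once. On simulated noise at the real probe positions, the caller recovered 70% of planted segments of 3 probes with a shift of 0.4 and 100% of those with 5 or more probes, with 0 false calls; that noise held no dye bias. In 6466 simulated windows, limma recovered 100% of planted shifts of 0.4 against the reference and 98% against the midparent, with 0 and 1 false calls. Those shifts were planted in every progeny, in independent normal noise of equal spread in parents and progeny. The arrays need not follow such noise, and a change in 1 offspring was not simulated.

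Alternatives planned before the data were examined were normexp background correction (offset 50), the deposited value table, a filter on probes well above background, each dye orientation alone, size thresholds of 0.2 and 0.5, another centring, 50 kb windows, at least 5 probes, a score of 8, slide as a random block, each progeny left out in turn, and each parent alone. Normexp had been planned on mean spot signals and was run on median spot signals. Chosen after seeing the data were regions of at least 10 probes, removal of the dye bias shared by the other mice, probe clusters with gaps of at most 2 kb as windows, and regions without progeny 2. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.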

Results

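Copy number was measured at selected loci in a family of C57BL/6JNrs mice, a father, a mother and 8 progeny, each against the same reference male. The series asks whether DNA copy number changes appear in the offspring of males kept under low dose-rate gamma rays. Its labels name a dose rate of 0.05 mGy per day for 400 days, while its design text lists the male of this family as non-irradiated. All values are log2 ratios of mouse over reference on build mm9, averaged over 2 arrays with swapped dyes. Each array measured 156258 probes, and the median processed intensity of the mouse channel ranged from 791 to 960.

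The sex chromosomes checked the labels and the direction of the ratio. The 48 X probes had a median log2 ratio of 0.01 in the father and 0.85 in the mother, and the 3 Y probes had medians of -0.02 and -1.42. Among the progeny, whose sex the labels do not give, progeny 7 had medians of 0.84 on X and -1.26 on Y, and progeny 8 had 0.83 and -1.33. The X medians of progeny 1 to 6 lay between -0.01 and 0.05, and their Y medians between -0.06 and 0.01. Against the male reference, progeny 7 and 8 thus matched the mother and read as female. Progeny 1 to 6 matched the father and read as male. The sex of the progeny rests on these probes alone.

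**Figure D1:**
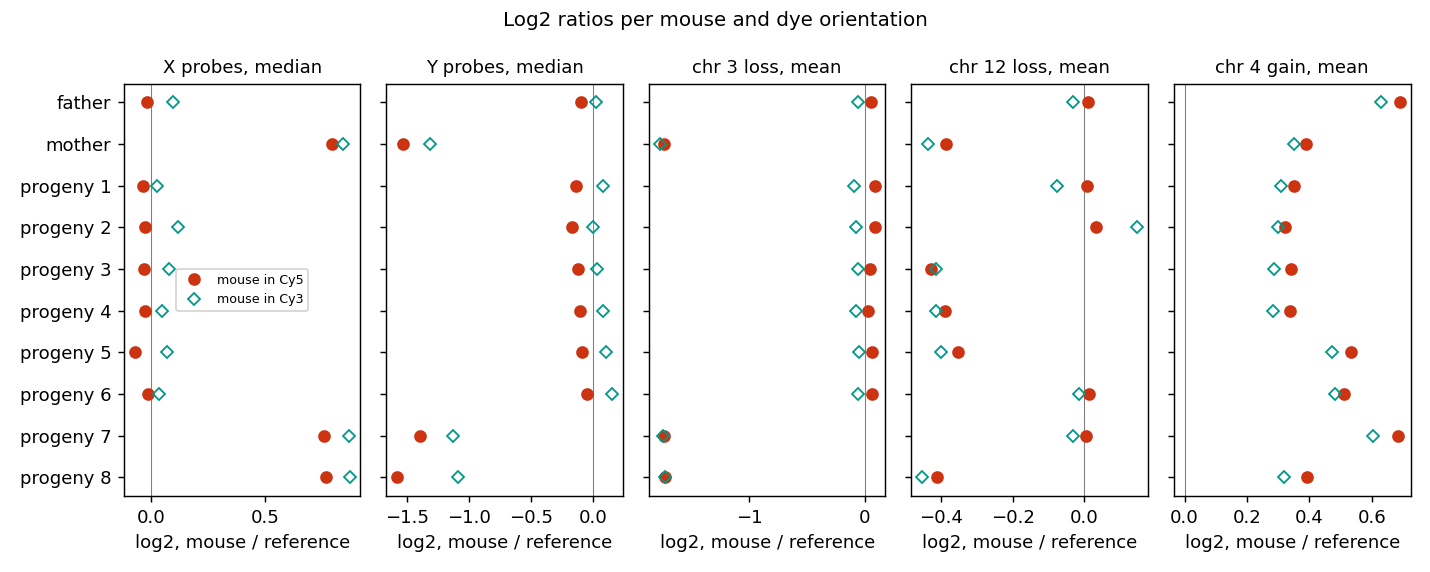
Log2 ratio of mouse over reference (horizontal axes, scaled separately per panel) in each of the 10 mice (rows), for the X and Y probe medians and the means over the regions on chromosomes 3, 12 and 4. Filled circles have the mouse in Cy5 and open diamonds in Cy3. The mother, progeny 7 and progeny 8 lie near -1.7 in the chromosome 3 panel, and all 10 mice lie above 0 in the chromosome 4 panel.

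The first comparison asked where the progeny as a group differed from the reference male. They carried more DNA over 1 stretch of chromosome 4, and no other autosomal window was called. In limma, 16 of 6466 windows were called, all higher, and all of them adjoined one another between 101110036 and 101269977. Their mean log2 ratios ran from 0.34 to 0.46 with standard errors of 0.03 to 0.04 and adjusted p from 0.0005 to 0.0008, and all 8 progeny were above 0 in each window. The highest was the window from 101220219 to 101229993, at 0.46 with a standard error of 0.04. Without the size requirement, 21 windows had an adjusted p under 0.05, a count that rested on single mice: it was 76 without progeny 2, 35 without progeny 6 and 18 to 20 without any 1 of the others, while the called windows numbered 16 or 17 throughout. Raising the size threshold to 0.5 left 0 windows. A gain over this reference is also what a lower copy number of the reference mouse would give. According to the design text, the array was built around probes that departed from the reference in this same family. The adjusted p therefore describe loci selected for such a departure and are no independent discovery among the windows.

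The called region spanned 161879 bp, from 101109089 to 101270967, with 1310 probes. Its mean log2 ratio was 0.66 in the father, 0.37 in the mother and 0.41 ± 0.13 (SD, n = 8) in the progeny. The progeny were not alike. Progeny 7 stood at 0.65, progeny 5 and 6 each at 0.50, progeny 8 at 0.35, progeny 1 at 0.33, progeny 3 at 0.32, and progeny 2 and 4 each at 0.31. The range over the 10 mice, 0.35, exceeded the largest difference between the dye orientations of a mouse, which was 0.08.

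**Figure D2:**
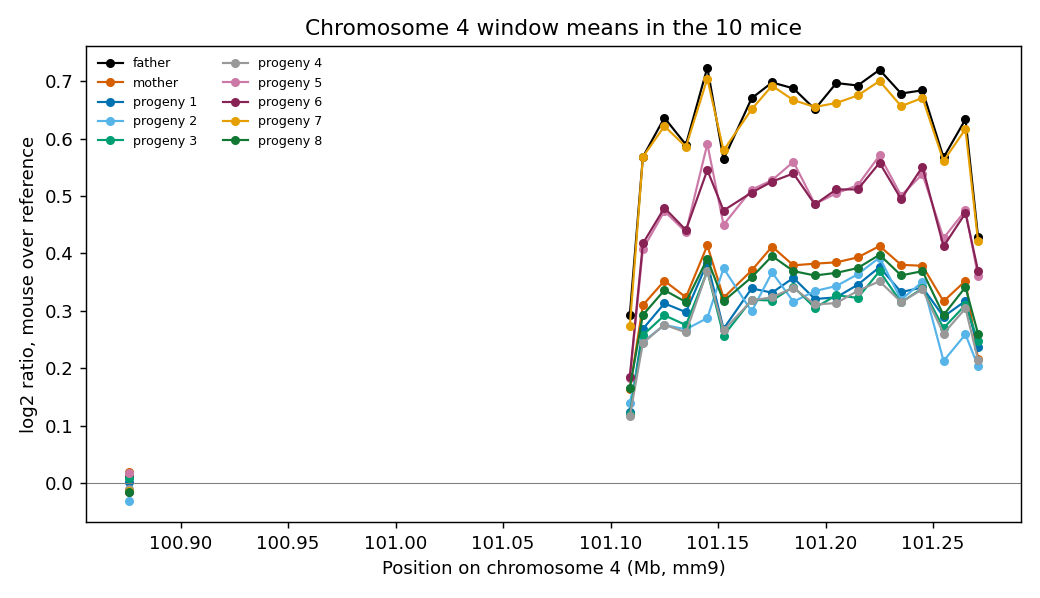
Mean log2 ratio of mouse over reference (vertical axis) of each 10 kb window against its position on chromosome 4 in Mb (horizontal axis), 1 colour per mouse, with lines joining neighbouring windows. The 10 mice lie near 0 in the flanking window on the left and above 0 from 101109089 on, with the father and progeny 7 at the top.

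The comparison of the progeny with the mean of their parents asked whether the offspring as a group departed from what they were born from. No window was called in limma (0 of 6466, with 27 at an unadjusted p under 0.05), and the smallest adjusted p was 1.00. The window with the smallest p, on chromosome 13 from 78197450 to 78198059, differed by 0.06 with a standard error of 0.02. The 27 are far fewer than the share of 0.05 of the windows that no difference at all would give. Without progeny 2 they numbered 216, also under that share. The test was therefore conservative, and its 0 calls do not show that no window departed. Both parents lay on 1 slide and all progeny on others, so slide and generation cannot be told apart. The share of mice that read as female also differed between parents and progeny. Loci divided by sex can therefore depart from the midparent by makeup alone, and they widen the spread between progeny. In the chromosome 3 window from 25420288 to 25424115, the mother and progeny 7 were at -1.96 and progeny 8 at -1.95, with the father at -0.01. Each parent was a single mouse, and a change carried by 1 offspring would not show in this test.

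The mother was lower than the father in 11 windows and higher in 0. Of these, 4 lay on chromosome 3, with differences from -1.95 to -1.06, 5 on chromosome 4 inside the gain, each at a difference of -0.31, 1 on chromosome 14 at -0.50 and 1 on chromosome 12 at -0.39. With 1 mouse each there was no test. Normexp background correction left 6 windows, all lower. A size threshold of 0.2 gave 28, of which 25 were lower and 3 higher in the mother.

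Calling each mouse on its own gave 129 regions over the family, 20 gains and 109 losses. Most were short: 93 held 3 probes, and 6 held 10 or more. Only the chromosome 4 gain was called in all 10 mice. There were 71 regions called in the mother and not the father, 4 in the father and not the mother, and 5 in both. The number of short calls has to be set against the dye bias. The difference between dye orientations, which holds no copy number, gave 809 autosomal calls in the 10 mice against 307 in the data, and 16 against 26 among calls of 10 or more probes. Progeny 2, with the noisiest array, gave 8 of those 16, and without it the numbers were 8 against 24. When the caller itself required 5 probes, the difference gave 447 calls against 190 in the data. When it required 10 probes, there were 33 against 49. When the dye bias shared by the other mice was removed, an alternative chosen after seeing the data, the order of all calls turned, with 107 between orientations against 661 in the data, and 1 against 27 among calls of 10 or more probes. That removal lowers the difference between orientations by construction. Without the removal, the difference keeps a dye bias that averaging the orientations reduces. None of the counts between orientations is therefore an estimate of the false calls in the data, whose number stays unknown. The number of regions was 284 with the shared dye bias removed, 72 with normexp correction and 58 at a score of 8.

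The deepest autosomal loss covered 31806 bp of chromosome 3, from 25416456 to 25448261, with 100 probes. Its mean log2 ratio was -1.75 in the mother, -1.74 in progeny 7 and -1.73 in progeny 8, and lay between -0.02 and 0.00 in the father and the other 6 progeny. These 3 mice were also those with raised X and lowered Y medians, so this loss divided the family by sex as read from those probes. In all, 45 regions on 16 chromosomes, 39 losses and 6 gains, were called in exactly the mother, progeny 7 and progeny 8, and no other set of 3 mice had more than 2. Over the 45 regions the median log2 ratio was -0.56 in the mother, -0.62 in progeny 7, -0.65 in progeny 8 and -0.01 in the father.

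Short losses in the same 3 mice made up most of the other deep regions. On chromosome 7, from 18817154 to 18817395, the mother was at -1.32, progeny 7 at -1.39 and progeny 8 at -1.37. The mean over these mice was -1.06 on chromosome 6 from 104241242 to 104241486, -1.04 on chromosome 3 from 132549431 to 132549728, -0.97 on chromosome 2 from 111694136 to 111694677, -0.95 on chromosome 1 from 148057968 to 148058609, -0.91 on chromosome 17 from 28879111 to 28879200 and -0.89 on chromosome 13 from 77818531 to 77818665. A loss on chromosome 1 was called in the same 3 mice but kept as 2 overlapping regions, because the calls shared too few probes to be merged. From 87991936 to 87992733 it was called in progeny 8 at -0.89, and from 87992674 to 87993226 in the mother at -0.75 and progeny 7 at -0.93. Losses on chromosomes 10 and 12 were divided over these mice in the same way. The only region on a sex chromosome, from 731532 to 1673709 on Y in progeny 7, held all 3 Y probes of the array. The call set their mean of -1.68 against their own median of -1.26, a difference of -0.42, and so does not show a loss of part of Y.

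A loss on chromosome 12 divided the progeny differently. It covered 7029 bp from 56384702 to 56391730, with 21 probes, and was called in the mother at -0.41, progeny 3 at -0.42, progeny 4 at -0.40, progeny 5 at -0.38 and progeny 8 at -0.43. The father was at -0.01, progeny 1 at -0.03, progeny 2 at 0.09, progeny 6 at 0.00 and progeny 7 at -0.01. The 2 dye orientations of a mouse differed by at most 0.12.

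The other regions called in the most mice were losses of 3 or 4 probes whose values were graded over the mice. On chromosome 3, from 5409869 to 5410050, the loss was called in 7 mice and ranged from -0.71 in progeny 8 to -0.34 in progeny 1, with progeny 6 at 0.11. Losses called in 6 mice lay on chromosome 16 from 51673930 to 51674476, with a mean of -0.37 in those mice, on chromosome 5 from 128944282 to 128944469, at -0.45, and on chromosome 18 from 67807912 to 67808505, at -0.33. A loss called in 5 mice lay on chromosome 5 from 16893302 to 16893566, at -0.55. Losses called in 4 mice lay on chromosome 2 from 10724809 to 10725306, at -0.49, and from 51993564 to 51994567, at -0.42. Progeny 6 had values above 0 in all of these short regions.

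**Figure D3:**
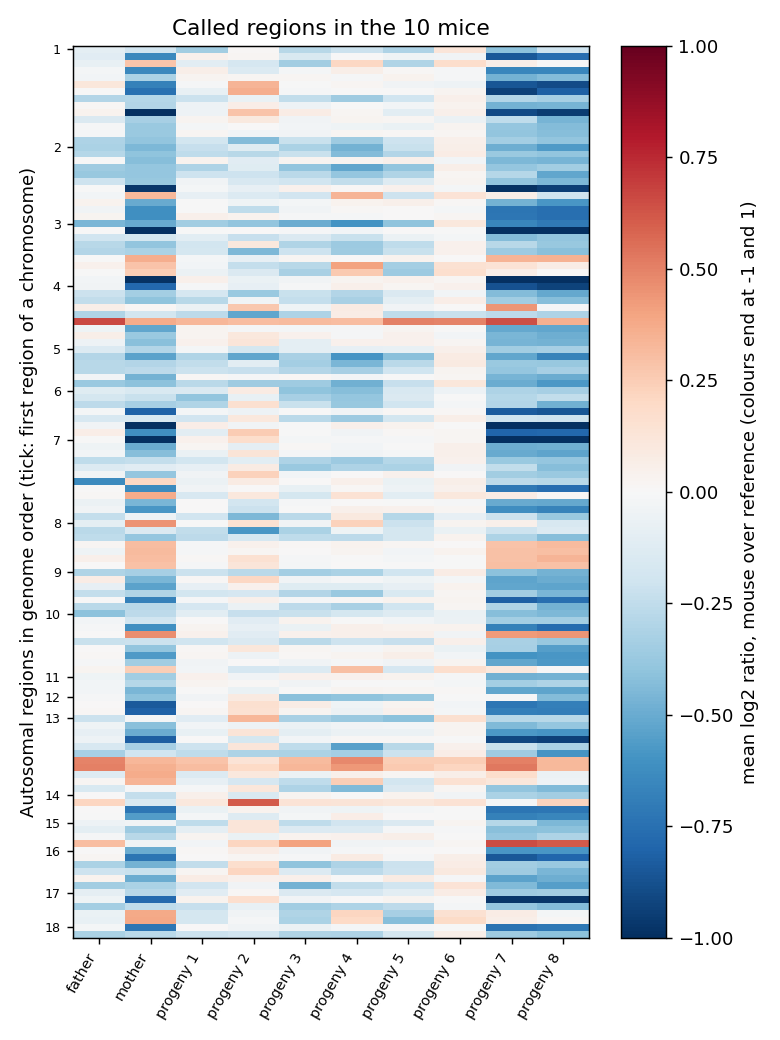
Mean log2 ratio of mouse over reference (colour, blue for loss and red for gain, ending at -1 and 1) of the 128 autosomal regions (rows, in genome order, with chromosome numbers on the vertical axis) in the 10 mice (columns). The columns of the mother, progeny 7 and progeny 8 hold most of the dark blue cells, and the chromosome 4 gain and 2 short regions on chromosome 13 are above 0 in all columns.

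Regions present in progeny and in neither parent are what the series screens for. There were 10, with 9 losses and 1 gain, and all were short, with 3 to 7 probes and scores of 6.09 to 7.62. The loss with the highest score lay on chromosome 13 from 115958261 to 115958409, at -0.44 in progeny 4 and -0.44 in progeny 8, with the father at -0.15 and the mother at -0.01, and progeny 7, not called, at -0.40. Losses called in 2 progeny also lay on chromosome 15 from 20962212 to 20962631, and on chromosome 6 from 21728764 to 21728966. On chromosome 15, progeny 8 was at -0.45 and progeny 4 at -0.19 over the 4 probes of the merged region, while the call in progeny 4 covered 3 of them, at -0.35. On chromosome 6, progeny 4 was at -0.68 with the mouse in Cy5 and -0.17 in Cy3, and progeny 3 at -0.59 and -0.22. The single gain lay on chromosome 4 from 38023423 to 38023809, at 0.44 in progeny 7, where father and mother were at 0.06 and 0.01. The region with the most probes, 7, was a loss on chromosome 8 from 87470235 to 87470643, at -0.58 in progeny 2, with the father at -0.27. That value rested on the noisy array of progeny 2, at -0.96 with the mouse in Cy3 against -0.20 in Cy5. The remaining 5 were losses called in 1 mouse each: on chromosome 16 from 56136023 to 56136156, at -0.46 in progeny 8, on chromosome 3 from 51516482 to 51516579, at -0.43 in progeny 7, on chromosome 6 from 87104411 to 87104726, at -0.37 in progeny 4, on chromosome 7 from 110473775 to 110473954, at -0.43 in progeny 8, and on chromosome 1 from 3766152 to 3766337, at -0.41 in progeny 7, where the orientations gave -0.65 in Cy5 and -0.17 in Cy3. In these 5 both parents were also below 0, at -0.23 to -0.09, and other progeny came close to the called one: progeny 7 at -0.35 on chromosome 16, progeny 8 at -0.39 on chromosome 3, progeny 3 at -0.27 on chromosome 6, progeny 3 at -0.37 on chromosome 7 and progeny 1 at -0.35 on chromosome 1. Over the 10 regions, 7 had a progeny that reached 0.3 in size without a call, and a parent reached up to 0.49 of the progeny value, where 0.5 would have counted as present. In 4 of the 10 regions a calling progeny was under 0.3 in size in 1 orientation, and in the chromosome 15 region progeny 4 was under it in both. At a score of 8 none of the 10 remained, and the 1 region then counted was another, a gain of progeny 2 on chromosome 14 that the father's call had kept out. Normexp correction gave 2 regions, of which only the chromosome 8 loss was among the 10. With the shared dye bias removed there were 29, which overlapped 5 of the 10. Of these 5, the losses on chromosomes 7 and 6 (from 21728764) were then called in 4 progeny each and the chromosome 3 loss in 2.

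The number of autosomal regions called per mouse was 9 in the father and 76 in the mother. In the progeny it was 1, 3, 13, 32, 8, 1, 76 and 86 for progeny 1 to 8. The noise in the score was 0.235 in progeny 2 and 0.091 to 0.121 in the other mice, so a call in progeny 2 needed a larger value. On chromosome 5 from 16893302 to 16893566, progeny 2 was not called at -0.52, while progeny 5 was called at -0.42. The counts are therefore not fully like measures over the mice. The difference of the progeny mean from the parents' mean was -15 regions (n = 8 and 2, two-sided exact permutation p = 0.756). The 3 highest counts were those of the mice with raised X medians, the mother, progeny 7 and progeny 8, which are 1 of 2 parents and 2 of 8 progeny. The father's 9 lay within the 1 to 32 of progeny 1 to 6, and the mother's 76 did not exceed the 76 and 86 of progeny 7 and 8. The sign of the pooled difference therefore follows the makeup of the 2 sets of mice. Over the 45 splits of the exact test, the difference was not larger than the spread between mice, which ran from 1 to 86 regions in the progeny. With only the arrays that had the mouse in Cy3 its sign turned, to 162.4, where progeny 2 alone had 2086 regions. Calling on 1 orientation drops the requirement on the other and keeps the noise of the difference between them, so that rule was looser. Parents and progeny lay on different slides, so an effect of the slide on these counts cannot be told apart from the generation.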

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

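The tests in this part were all chosen after the results they address had been seen. Among 38 measures compared over the 8 progeny, 3 had 1 mouse standing apart. Chance marks about 1 in 20 among measures not picked for their values. Most of the 38 were regions named by their calls, so that rate is no standard here. Of the 3 flags, 2 concern the same array. The progeny 2 array with the mouse in Cy3 had a log2 ratio SD of 0.441, against 0.127 to 0.162 on the other progeny arrays of that orientation. Its derivative SD, the spread between neighbouring probes, was 0.304, against 0.0994 to 0.124. The short loss on chromosome 3 from 5409869 to 5410050 stood at 0.107 in progeny 6, against -0.71 to -0.34 in the other 7 progeny.

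The regions shared by the mother, progeny 7 and progeny 8 were weighed against inheritance, slide and sex chromosome sequence. If they were maternal copy number changes passed on independently, they would fall to many sets of progeny, but of the 64 regions called in the mother, not in the father and in at least 1 progeny, which lay on 18 chromosomes, 70.3% were called in exactly progeny 7 and 8. A homozygous autosomal deletion in the mother at the chromosome 3 region would leave every progeny lowered, yet the highest progeny stood at 0.00398. A slide effect would leave mother and father, who shared a slide, alike; over the 57 losses called in both progeny 7 and progeny 8, chosen without regard to either parent, the median of mother minus father was -0.456 (quartiles -0.68 and -0.24), with the mother lower in 53. Sequence shared with the X or Y chromosome may account for the pattern. Outside these 3 mice the highest X median was 0.0504, and the largest of the 6 gains, 0.47, stayed below the X medians of the 3. The X medians had already set these 3 mice apart, so the first value could not have gone against the explanation. The chromosome 3 loss stood at -1.75 in the mother, -1.74 in progeny 7 and -1.73 in progeny 8. Their Y medians were less deep, at -1.42, -1.26 and -1.33, while the means of the 3 Y probes were -1.70, -1.68 and -1.66. Inside the loss, the window from 25420288 to 25424115 was at -1.96 in the mother, deeper than both the median and the mean of her Y probes. The Y probes therefore set no clear bound for the losses. No sequence was compared, so shared sequence stays a hypothesis.

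The chromosome 4 gain was weighed as a copy number of the reference mouse, as a slide effect and as inherited copy number. A difference in the reference alone gives 1 value in all mice, whereas the range was 0.349 against a largest dye difference of 0.0805, which leaves open a contribution of the reference to the part common to all mice. On 2 of the 5 slides the mice differed, by 0.290 (progeny 7 and 8) and 0.288 (father and mother), which a slide effect as the whole cause forbids; on the other 3 slides they were alike, with differences of 0.019, 0.0042 and 0.0050, so a part played by the slide, as for progeny 5 and 6 at 0.50, stays open. Additive transmission would make the lowest and highest progeny add up to the parents. On the linear scale the sums were 2.80 and 2.87 and differed by -0.0679, within a tolerance set after the values were seen. Any spread of progeny centred near the mean of the parents would pass as well. The check therefore does not separate transmission from a part played by the slide. Parents carrying chromosomes of unequal copy number stay a hypothesis found in the same data.

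The chromosome 12 loss was weighed as a slide effect and as a loss passed on by the mother. On 3 of the 5 slides the mice differed by 0.417 (progeny 7 and 8), 0.40 (father and mother) and 0.375 (progeny 5 and 6), each over 3 times their largest dye difference, while progeny 3 and 4 differed by 0.018 and progeny 1 and 2 by 0.123. The 4 of 8 progeny called do not depart from even odds of transmission (exact two-sided binomial p = 1), a test with little power at 8 mice. A loss of 1 of 2 copies at full response is argued against by the deepest value, -0.431, where a doubling of X gave 0.85 in the mother. Probes that also bind another copy of the sequence could lower the response and were not tested.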

How the results depend on the processing

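Probe clusters as windows, at least 10 probes, removal of shared dye bias and regions without progeny 2 were chosen after seeing the data; the other alternatives were planned. The midparent comparison gave 0 called windows in limma under every alternative run, with each parent alone and with each progeny left out, while leaving out progeny 2 raised the windows at an unadjusted p under 0.05 from 27 to 216. Both counts are under a share of 0.05 of the windows, so the test was conservative. Against the reference, 16 windows became 4 with 50 kb windows, 2 with probe clusters and 0 at a size of 0.5, and 16 to 17 with 1 progeny left out; with adjusted p alone the 21 became 76 without progeny 2 and 35 without progeny 6. Wider windows and clusters count the same stretch fewer times. Mother against father, 11 windows became 28 at a size of 0.2, 5 at 0.5, 6 with normexp, 2 with 50 kb windows and 2 with clusters.

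The count of 129 regions became 72 with normexp, 61 at a size of 0.5, 58 at a score of 8, 80 with at least 5 probes, 18 with at least 10 and 284 with shared dye bias removed. The count of 10 regions in progeny and in neither parent became 2 with normexp, 3 with the background filter, 1 at a size of 0.5, 1 at a score of 8, 2 with at least 5 probes, 2 with at least 10 and 29 with dye bias removed. These are partly other regions: those overlapping 1 of the 10 numbered 1 with normexp, 2 with the filter, 0 at a size of 0.5, 0 at a score of 8, 2 with at least 5 probes, 1 with at least 10 and 5 with dye bias removed. The cause was not tested. A single orientation, which keeps its dye bias, gave 1073 (Cy5) and 2680 (Cy3) regions, and 192 and 1870 in progeny alone, of which 3 and 3 overlapped 1 of the 10. With Cy3 alone the progeny minus parent difference in regions per mouse turned from -15 to 162.4 (exact permutation p = 0.911), as progeny 2 alone had 2086. Its sign held in the other alternatives, and without progeny 2 it was -11.5. With the dye bias removed there were 661 calls against 107 between orientations, and 27 against 1 for calls of 10 or more probes. Of 30 recomputed values of the chromosome 3, 4 and 12 regions, 0 changed sign and 29 moved less than a set limit. For the progeny mean the limit was the SD between progeny, and for a parent the difference between its own dye orientations. A single orientation of a parent lies within that difference by construction, so those values are no check. Gene lists were not run, since the files used here name no genes. No paired analysis was possible because each parent is a single mouse and no replicate numbers pair it with progeny.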

Other observations

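The regions in this part were chosen after their values had been seen. On chromosome 13, 2 short overlapping gains of 3 probes each, from 95705166 to 95707524 and from 95707465 to 95707908, had values above 0 in all 10 mice. The second was called in the father at 0.50 and in progeny 7 at 0.53, and the first in progeny 4 at 0.48; the mother stood at 0.33 and 0.35. On chromosome 8, 4 gains between 102185153 and 102235637 were called in the mother, progeny 7 and progeny 8, at values of 0.29 to 0.34, with the father between -0.04 and 0.05. On chromosome 10, from 83368007 to 83368508, the gain in the same mice was 0.47 in the mother, 0.43 in progeny 7 and 0.44 in progeny 8.

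On chromosome 14, a gain of 13 probes from 52008524 to 52021220 was called in the father and in progeny 2. The father's mean over the region was 0.22 (0.36 with the mouse in Cy5 and 0.07 in Cy3). Progeny 2 was at 0.61 (0.50 in Cy5 and 0.73 on its noisy Cy3 array), and the mother at -0.16. Progeny 8, not called, was at 0.22. In every mouse but progeny 2 the Cy5 value was the higher, as in progeny 6 at 0.47 against -0.18, so the region carried dye bias. On chromosome 15, from 85062032 to 85062220, a gain of 3 probes was called in progeny 7 at 0.65, progeny 8 at 0.61 and progeny 3 at 0.40. The father stood at 0.31 without a call, and the mother at -0.03.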
